A study of Mus musculus with 8 samples.

How the data were processed

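RNA sequencing libraries of 8 samples of mouse fibro/adipogenic progenitors (FAPs) were analysed, 5 from the FAP-ctrl group and 3 from the FAP-no cilia group. Per the labels, the cells came from the tibialis anterior muscle of mice of mixed background 3 days after a glycerol injury, and total RNA was made into stranded total RNA libraries and sequenced with single-end reads of 50 bases. Per the series design text, the authors aligned the reads with STAR to the GRCm38 mouse genome and normalized the read counts with DESeq to the geometric mean over all samples. The tool that counted reads per gene, its strand setting and the annotation release of the gene identifiers are not given in the sources used here. Without a stated strand setting, the counts of a gene and of an antisense or overlapping partner such as Kdm6bos may not be separable.

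The deposited files hold a signal per gene that is a read count divided by a size factor, 1 value for each of 37991 genes per library. In every library each value was a whole multiple of the value of 1 read, with 100% of values whole within a tolerance of 0.01 reads and a largest deviation of 7.78e-05 reads. The reads recovered in this way summed to between 15.3 M reads (FAP-no cilia 2) and 43.9 M reads (FAP-ctrl 1) per library, 223 M over the 8 libraries and 27.9 M on average. Median-of-ratios size factors of the recovered reads differed from those in the deposited values by at most 5.02e-11 in relative terms, so the deposited values were normalized over these 8 libraries together. The depth of the libraries sets the precision of low values: 1 read was worth 0.610 normalized reads in FAP-ctrl 1 and 1.79 in FAP-no cilia 2. Gene symbols, types and coordinates were taken by gene identifier from a GENCODE annotation of GRCm38 which may be later than the one used by the authors, and 32919 of the 37991 identifiers were matched.

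Because the deposited values are normalized, the test fixed for such values was used. Genes were kept at a value of at least 10 in at least 3 libraries, which left 14768 genes. The values were transformed to log2(value + 1) and FAP-no cilia was compared with FAP-ctrl by limma-trend with genotype as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are given as FAP-no cilia minus FAP-ctrl with the standard error (SE) of the limma fit. Means and standard deviations (SD) are of normalized read counts. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

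A set of 30 gene lists was fixed before the data were examined, as were the main test, most of the alternatives below and the rule for named genes. The lists cover the Hedgehog pathway, cilium components, adipogenesis, matrix and proteases, FAP identity, growth and stress programmes, and markers of other cell types of injured muscle; 680 of the 686 listed symbols were found. Each list was tested with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry were run beside it, the former also in the limma-trend alternatives with other libraries or model terms, and members were also adjusted over the list alone. With an estimated correlation, camera also rests on the few residual degrees of freedom of the libraries, so it calls fewer lists even at a low correlation. Named genes were Ift88, Gli1, Ptch1, Hhip, Timp3, Mmp14, Pparg, Cebpa and Pdgfra in any case; 1 more gene of this part is not reported here. They also included up to 10 genes in each direction with the largest change among those past the threshold, with a symbol, a mean of at least 20 and groups that did not overlap. Predicted genes, pseudogenes named -ps, small RNAs and sex-linked genes were left out of this part. As 0 genes met this in either direction, the 5 with the smallest p in each were named instead and do not pass. Up to 4 members of each list called by camera could be named as well. Any gene outside this rule is said to have been chosen after its values were seen.

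Replicates of 1 group were compared by a chi-square test of their reads over genes. The statistic per degree of freedom lay between 18.1 and 95.0 for all pairs, so no library was a copy of another. The labels do not say whether each library came from a separate animal, and the p-values then measure the spread between these libraries. The sex of the mice was read from Xist and 4 Y-linked genes. Both groups share the replicate numbers 1 to 3, and deviations from the group means of libraries with the same number were checked for correlation.

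Alternatives fixed beforehand were other pseudocounts and filters, edgeR with RLE and upper-quartile factors and with other filters, DESeq2, limma-voom without and with quality weights, the replicate number as a block, a test against a fold of 1.5, and leaving out each library. A sex covariate was to be used only if both groups held both sexes. This was not so, and it was run only as an alternative added after the data were seen. FAP-no cilia held male libraries only. With this covariate the difference therefore comes from the 2 male FAP-ctrl and the 3 FAP-no cilia libraries. The other added alternatives were edgeR with TMM factors on the recovered reads, with and without robust dispersions, DESeq2 with sex as a covariate, and the 5 male libraries alone. The edgeR test with TMM factors and robust dispersions called 0 genes, with 1493 at an unadjusted p under 0.05, and without robust dispersions it called 1.

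The scripts were tested on simulated counts drawn from the means, dispersions and size factors of these libraries, with 200 genes changed per simulation, each with a mean of at least 50. In 10 simulations of this comparison, limma-trend recovered 26.4% of genes changed by 1.5-fold, 73.1% of genes changed by 2-fold and 97.1% of genes changed by 4-fold, on 14717 genes on average, and 6.03% of its calls were false. DESeq2, run on 2 of the simulations, recovered 51.5%, 88.8% and 97.0%, and 18.6% of its calls were false. A limit on false calls in this check was first set for all 3 tools, DESeq2 exceeded it, and the limit was then kept for limma and edgeR alone, whose false shares were 6.03% and 6.58%. Genes were simulated independently of each other, so the preset correlation of camera was not tested in this way.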

Results

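The libraries profile fibro/adipogenic progenitors, a mesenchymal cell population of skeletal muscle that can give rise to fibroblasts and adipocytes. The cells were purified from the tibialis anterior muscle 3 days after glycerol injury, a treatment that damages muscle fibres and is followed by fat formation. Per the labels, the primary cilium was removed in the FAP-no cilia group through a floxed allele of Ift88, which encodes a component of the intraflagellar transport machinery, and FAP-ctrl cells came from wild type muscle. The 5 FAP-ctrl libraries held 25.2 to 43.9 M gene reads and the 3 FAP-no cilia libraries 15.3 to 29.5 M. The comparison of the groups addresses which transcripts differ in FAPs without cilia, with Hedgehog signalling and injury-induced adipogenesis as the subject of the series.

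Ift88 (ENSMUSG00000040040, chromosome 14, 57424062 to 57517936, GRCm38) was lower in each FAP-no cilia library than in any FAP-ctrl library. Its normalized read count was 477, 457, 540, 566 and 594 in FAP-ctrl and 211, 195 and 322 in FAP-no cilia. The group means were 527 ± 58.4 (SD, n = 5) and 243 ± 69.3 (SD, n = 3). The log2 difference of -1.14 ± 0.17 (SE) did not pass the all-gene threshold in limma-trend (adjusted p = 0.0895). Without FAP-no cilia replicate 3, the library with the highest Ift88 of its group, the difference was -1.37 and passed (adjusted p = 0.0214), and DESeq2 called it with all libraries (adjusted p = 8.12e-06). The counts are per gene, so reads of exons inside and outside the floxed part were not told apart. The share of cells in FAP-no cilia that kept Ift88 and a cilium was not measured here, and its values may include such cells.

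**Figure D1:**
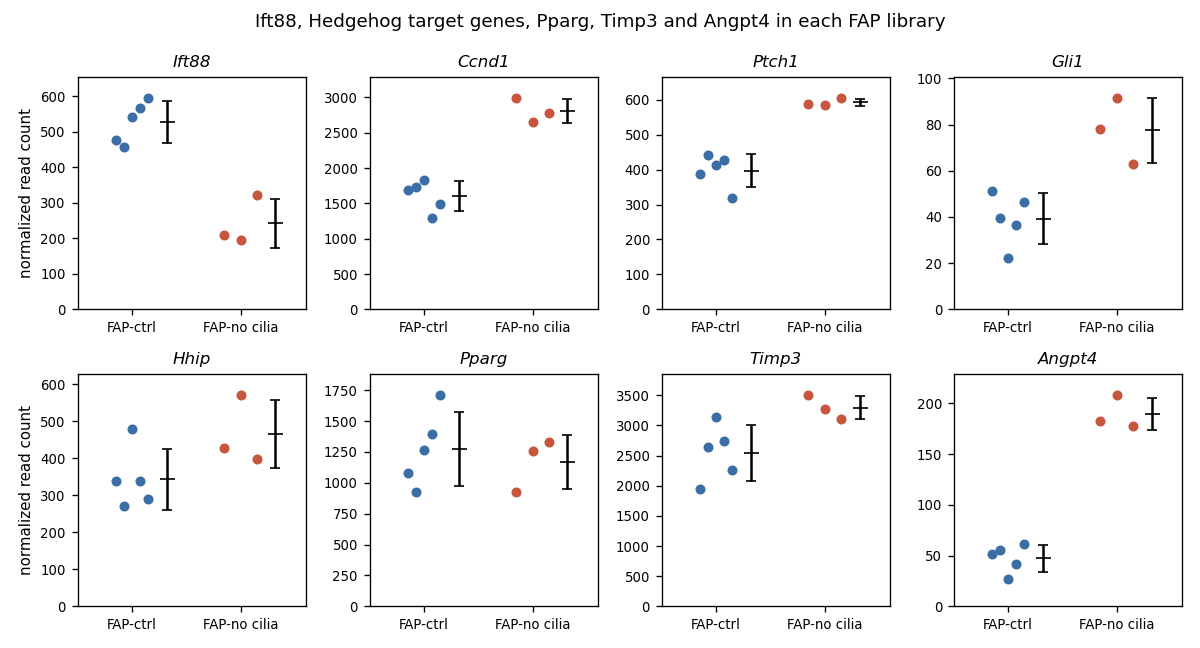
Normalized read counts (vertical axes, linear from 0) of 8 genes in each of the 5 FAP-ctrl and 3 FAP-no cilia libraries (points), with the group mean and SD (black bars). Ift88 lay between 457 and 594 in FAP-ctrl and between 195 and 322 in FAP-no cilia, and Angpt4, Ccnd1, Ptch1 and Gli1 were higher in every FAP-no cilia library than in any FAP-ctrl library.

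Of the 14768 genes tested, 1 passed the adjusted threshold, 0 of them higher and 1 lower in FAP-no cilia. This was Rps24-ps3, named here after its values were seen, a processed pseudogene of the ribosomal protein gene Rps24 on the X chromosome (79195047 to 79195448, GRCm38). Rps24-ps3 had a normalized read count of 744 ± 396 (SD, n = 5) in FAP-ctrl and 4.87 ± 2.91 (SD, n = 3) in FAP-no cilia, a log2 difference of -6.92 ± 0.52 (SE, adjusted p = 0.00139). Its sequence is nearly identical to that of Rps24, so the assignment of its reads is uncertain, and it did not pass with robust edgeR and TMM factors (log2 difference -7.14, adjusted p = 0.0973) or limma-voom (-6.89, adjusted p = 0.353). At an unadjusted p under 0.05, limma-trend had 691 genes higher and 900 lower. DESeq2 on the recovered reads called 177 genes, 74 higher and 103 lower, and edgeR with TMM factors called 0 with robust dispersions, with 1493 at an unadjusted p under 0.05, and 1, Rps24-ps3, without them (adjusted p = 0.0336). The groups did not overlap for 535 genes that were higher and 545 that were lower in FAP-no cilia, 7.31% of the genes tested. Chance gives 3.57% on average over all splits of the libraries into 3 and 5. The spread of this share between splits was not computed, so an excess over chance was not tested.

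Under the rule for named genes, which leaves out Rps24-ps3, the genes with the smallest p in each direction did not pass the threshold in limma-trend. Angpt4, which encodes a ligand of the Tie2 receptor, stood at 47.5 ± 13.5 (SD, n = 5) in FAP-ctrl and 190 ± 16.1 (SD, n = 3) in FAP-no cilia, a log2 difference of 2.03 ± 0.26 (SE, adjusted p = 0.0895). Penk, the precursor of the enkephalin peptides, stood at 456 ± 80.5 and 944 ± 156, and Grb14, an adaptor of the insulin receptor, at 199 ± 29.7 and 408 ± 68.5 (SD). Scara5, a scavenger receptor, stood at 2638 ± 369 and 4639 ± 652 (SD). The adjusted p of Penk, Grb14 and Scara5 was 0.0895 for each. In the other direction, the transporter gene Slco5a1 had a log2 difference of -1.33 ± 0.20, the antisense transcript Kdm6bos -1.18 ± 0.18, Ccdc30 -1.18 ± 0.18 and the metalloprotease gene Adamts19 -2.53 ± 0.39 (SE), each at an adjusted p of 0.0895. DESeq2 gave these 8 genes and Ccnd1 adjusted p-values between 4.33e-12 and 0.000299.

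The Hedgehog target genes rose as a list in FAP-no cilia, with 10 of 14 tested members higher and a median log2 difference of 0.17 (camera adjusted p = 0.00561). With an estimated correlation the list was not called (adjusted p = 0.499). Without FAP-no cilia replicate 3 its median was 0.18 and it was not called either (adjusted p = 0.0617), and without FAP-no cilia replicate 1 the median was 0.28. The lowest median with a library left out was 0.12, without FAP-no cilia replicate 2 (camera adjusted p = 0.0359). Over all genes limma-trend called 0 members and DESeq2 called 2, and adjusted over the list alone 4 members passed, all of them higher. The DESeq2 calls were Ccnd1 and Ptch1. With sex as a covariate DESeq2 kept Ccnd1 (adjusted p = 0.0176) and lost Ptch1 (adjusted p = 0.394). Ccnd1, the cyclin of the entry into the cell cycle, stood at 1609 ± 215 (SD, n = 5) and 2810 ± 167 (SD, n = 3), a log2 difference of 0.81 ± 0.11 (SE). Ptch1, the Hedgehog receptor and itself a target of the pathway, stood at 397 ± 48.3 and 592 ± 10.4 (SD), a log2 difference of 0.58 ± 0.12 (SE, adjusted p = 0.163). Gli1, a transcription factor induced by the pathway, stood at 39.2 ± 11.1 and 77.6 ± 14.2 (SD), a log2 difference of 1.0 ± 0.29 (SE, adjusted p = 0.261). Nrp2 had a log2 difference of 0.24 ± 0.08 (SE, adjusted p = 0.318). Hhip, a Hedgehog-binding inhibitor, had a difference of 0.45 ± 0.19 (SE, adjusted p = 0.435), with values that overlapped between the groups. The 19 tested Hedgehog pathway components were not called, with a median of 0.0037 (camera adjusted p = 0.669).

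Neither adipogenic genes nor the matrix and protease lists were called. Pparg and Cebpa, the transcription factors at the head of adipocyte differentiation, differed by less than the spread between replicates: Pparg stood at 1273 ± 302 and 1170 ± 217 and Cebpa at 1535 ± 149 and 1635 ± 310 (SD). The log2 difference of Pparg was -0.11 ± 0.19 (SE) and that of Cebpa 0.077 ± 0.13 (SE), and both signs turned under some alternatives. Of 29 tested adipogenic genes 15 were higher and 14 lower, with a median of 0.016 (camera adjusted p = 0.998), and the median of the anti-adipogenic regulators was -0.059 (adjusted p = 0.979). Timp3, an inhibitor of metalloproteinases, stood at 2544 ± 461 (SD, n = 5) and 3295 ± 194 (SD, n = 3), a log2 difference of 0.39 ± 0.14 (SE, adjusted p = 0.365). The highest FAP-ctrl value of Timp3 was 3142 and the lowest FAP-no cilia value 3114. Mmp14, a membrane-bound metalloproteinase, stood at 11942 ± 1860 and 12414 ± 531 (SD), a log2 difference of 0.069 ± 0.13 (SE). The tissue inhibitors of metalloproteinases (5 tested, median -0.029, adjusted p = 0.669) and the matrix metalloproteinases and ADAM proteases (29 tested, median -0.00098, adjusted p = 0.791) were not called. Extracellular matrix and fibrosis genes had a median of 0.024 over 34 tested members (adjusted p = 0.979), and in the male libraries alone a median of -0.14 (adjusted p = 0.000292; adjusted p = 0.522 with an estimated correlation). TGF-beta and BMP signalling (median 0.070, adjusted p = 0.381) and Wnt target genes and antagonists (median -0.11, adjusted p = 0.791) were not called in the main test. The TGF-beta and BMP list was called with edgeR without a filter at the preset correlation (adjusted p = 0.0429; adjusted p = 0.740 with an estimated correlation in the limma-trend fit). Its median was 0.0045 without FAP-ctrl replicate 5, 0.022 without FAP-no cilia replicate 1 and 0.11 without FAP-no cilia replicate 3.

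Pdgfra, the surface marker of FAPs, stood at 43297 ± 7050 (SD, n = 5) in FAP-ctrl and 41860 ± 2003 (SD, n = 3) in FAP-no cilia, a log2 difference of -0.034 ± 0.15 (SE). The 22 FAP identity markers were not called (median 0.051, adjusted p = 0.797); Thy1, chosen after its values were seen, was the only 1 of them to pass adjusted over the list alone, with a log2 difference of 0.41 ± 0.09 (SE). The other genes of the cilium did not move as lists. The 28 intraflagellar transport genes other than Ift88 had a median of 0.00084, with 14 higher and 14 lower (adjusted p = 0.669), and the 25 BBSome and transition zone genes a median of -0.040 (adjusted p = 0.504). The median, the mean and the camera direction of a list differed in sign for 6 lists, none of them called: Hedgehog pathway components, intraflagellar transport, adipogenic genes, anti-adipogenic regulators, tissue inhibitors of metalloproteinases, and extracellular matrix and fibrosis.

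Several growth and metabolic lists rose in FAP-no cilia by camera with the preset correlation, by small amounts. Of 40 cell cycle genes 39 were higher, with a median log2 difference of 0.14 (adjusted p = 6.23e-08; adjusted p = 0.499 with an estimated correlation). Ube2c, which serves the anaphase-promoting complex, stood at 1126 ± 71.4 and 1477 ± 118 (SD) and was the only 1 to pass adjusted over the list alone; Tyms, a thymidylate synthase, had a log2 difference of 0.26 ± 0.08 (SE). All 28 hypoxia and glycolysis genes were higher, with a median of 0.32 (adjusted p = 3.72e-08; adjusted p = 0.590 with an estimated correlation), and of 0.20 without FAP-no cilia replicate 1. Among these, the glycolytic enzyme gene Pgk1 stood at 8756 ± 1146 and 12167 ± 2557 and Pgam1 at 2160 ± 216 and 2824 ± 296 (SD). Of 24 unfolded protein response genes 23 were higher, with a median of 0.18 (adjusted p = 0.00013; adjusted p = 0.608 with an estimated correlation), and 20 of 23 cholesterol biosynthesis genes were higher, with a median of 0.17 (adjusted p = 0.000291; adjusted p = 0.608 with an estimated correlation). The cholesterol list had a median of 0.082 and lost its call without FAP-no cilia replicate 2 (adjusted p = 0.0507), and its median was 0.11 without FAP-ctrl replicate 2. Insig1, a regulator of sterol synthesis, had a log2 difference of 0.39 ± 0.11 and Dnajb11, a chaperone of the endoplasmic reticulum, 0.28 ± 0.12 (SE). In each of these 4 lists limma-trend called 0 genes over all genes tested, and DESeq2 called 1, Ube2c.

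Inflammatory genes and macrophage markers rose by the same test. Of 31 cytokines and inflammatory genes 28 were higher, with a median of 0.40 (adjusted p = 2.23e-06; adjusted p = 0.590 with an estimated correlation), and of 0.15 without FAP-no cilia replicate 1. Saa3, an acute-phase protein gene, stood at 450 ± 200 (SD, n = 5) and 1331 ± 620 (SD, n = 3) and passed adjusted over the list alone, as did no other member, and Ccl11, an eosinophil chemokine, stood at 5311 ± 1006 and 7629 ± 1483 (SD). Of 23 macrophage and monocyte markers 22 were higher, with a median of 0.94 (adjusted p = 3.61e-05; adjusted p = 0.608 with an estimated correlation). The list's median per library, as a log2 deviation from the mean of each gene, ranged from -1.43 to 0.72 in FAP-ctrl and was -0.11, 1.62 and 0.32 in FAP-no cilia. Without FAP-no cilia replicate 2 the macrophage list had a median of 0.30 and was not called (adjusted p = 0.123). Itgam, an integrin of myeloid cells, stood at 71.1 ± 43.8 and 182 ± 126 (SD). Of 28 interferon-stimulated genes 27 were higher, with a median of 0.34 (adjusted p = 0.00276; adjusted p = 0.794 with an estimated correlation), and the call was lost without FAP-ctrl replicate 4 (median 0.15, adjusted p = 0.273) or FAP-no cilia replicate 3 (median 0.17, adjusted p = 0.375). The interferon call was also lost in 4 edgeR fits (medians 0.19 to 0.21, adjusted p = 0.0625 to 0.119). The interferon median was 0.60 without FAP-ctrl replicate 3 and 0.52 without FAP-no cilia replicate 1. Immediate early and dissociation stress genes had a median of 0.19 with 18 of 28 higher (adjusted p = 0.036; adjusted p = 0.740 with an estimated correlation) and lost the call without FAP-ctrl replicate 3 (0.15) or 4 (0.11) or FAP-no cilia replicate 1 (0.19) or 3 (0.15), with the median in parentheses. Hspa8, a heat shock chaperone, had a log2 difference of 0.42 ± 0.12 (SE) and Egr2 one of -0.46 ± 0.12 (SE).

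**Figure D2:**
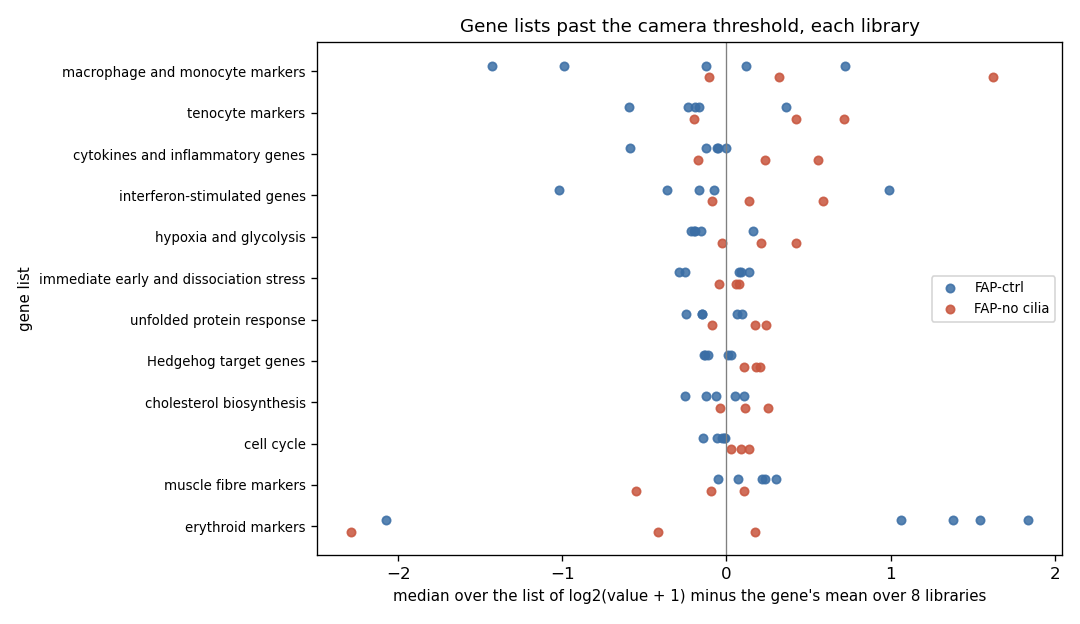
Median over each gene list of log2(value + 1) after subtraction of the mean of each gene over 8 libraries (horizontal axis, log2 units), for the 12 lists past the camera threshold; each point is a library of FAP-ctrl or FAP-no cilia. The groups do not overlap in the Hedgehog target and cell cycle lists and overlap in the others, and the macrophage median reaches 1.62 in FAP-no cilia 2.

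Among markers of other cell types, all 10 tested tenocyte markers were higher in FAP-no cilia, with a median of 0.57 (adjusted p = 0.00168; adjusted p = 0.590 with an estimated correlation). Prg4, which encodes the joint lubricant lubricin, stood at 11222 ± 2251 and 19911 ± 6059 and Fmod, a small proteoglycan of tendon, at 1575 ± 412 and 2491 ± 183 (SD), and these 2 passed adjusted over the list alone. Without FAP-no cilia replicate 3 the tenocyte list had a median of 0.30 and was not called (adjusted p = 0.217). Muscle fibre markers fell, with 12 of 14 lower and a median of -0.47 (adjusted p = 0.0249; adjusted p = 0.590 with an estimated correlation), and lost the call without FAP-no cilia replicate 1 (median -0.40, adjusted p = 0.160), with genes of a mean of at least 50 (median -0.22, adjusted p = 0.161) and in 5 edgeR fits (medians -0.47 to -0.28, adjusted p = 0.0568 to 0.289). Ttn, the giant sarcomere protein gene, stood at 80.3 ± 35.9 and 30.3 ± 25.4 (SD). The 5 tested erythroid markers fell, with a median of -1.81 (adjusted p = 0.0433; adjusted p = 0.608 with an estimated correlation). They lost the call without any 1 of FAP-ctrl replicates 1 to 4 (medians -1.64 to -1.41) or of FAP-no cilia replicates 1 (-1.62) and 3 (-1.23), and had a median of -2.91 without FAP-ctrl replicate 5. The erythroid call was also lost without a filter on low values (-0.72, adjusted p = 0.0524), with a pseudocount of 0.1 (adjusted p = 0.0576) and with limma-voom without (adjusted p = 0.066) and with quality weights (adjusted p = 0.0541). FAP-ctrl 5 (-2.08) and FAP-no cilia 3 (-2.29) had the lowest medians per library. The haemoglobin gene Hbb-bs stood at 112 ± 70.9 and 21.7 ± 18.9 (SD).

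The remaining lists were not called in the main test. Endothelial markers had a median of 0.35 (adjusted p = 0.193), with a deviation of 1.76 in FAP-no cilia 3 and of -0.58 to 0.15 in the other libraries. They were higher and called in 11 of 27 other settings, among them each edgeR fit (medians 0.77 to 0.87) and DESeq2 (0.85, adjusted p = 7.95e-06; adjusted p = 0.794 by camera with an estimated correlation on the limma-trend fit). Their median was 1.05 without FAP-no cilia replicate 1 (adjusted p = 0.000212), 0.45 without replicate 2 (adjusted p = 0.0359) and -0.28 without replicate 3 (adjusted p = 0.410), and the first 2 of these were not called with an estimated correlation (adjusted p = 0.563 and 0.747). Satellite cell and myoblast markers had a median of -0.45 (adjusted p = 0.381), and Itga7, chosen after its values were seen, was the only member to pass adjusted over the list alone, at 212 ± 22.8 and 129 ± 38.4 (SD). The satellite cell median was -0.23 without FAP-no cilia replicate 2 and -0.20 without replicate 3, and the list was lower and called by DESeq2 with sex as a covariate (-0.52, adjusted p = 0.0117; adjusted p = 0.464 with an estimated correlation in the limma-trend fit with sex). Schwann and neural markers had a median of -0.40 (adjusted p = 0.0517) and were lower and called in 4 other settings: DESeq2 (-0.42, adjusted p = 0.0326), edgeR without a filter (-0.45, adjusted p = 0.0479), without FAP-ctrl replicate 1 (-0.41, adjusted p = 0.0407) and without FAP-no cilia replicate 3 (-0.47, adjusted p = 0.0264). The last 2 were not called with an estimated correlation (adjusted p = 0.607 and 0.482), nor was the list in the main limma-trend fit (adjusted p = 0.590), and without FAP-no cilia replicate 1 the median was -0.21. The list of neutrophil and lymphocyte markers had a median of -0.51 over 6 tested members (adjusted p = 0.202), and pericyte and smooth muscle markers 0.023 (adjusted p = 0.669). Mitochondrially encoded genes had a median of -0.21 with 12 of 12 lower (adjusted p = 0.381). Their median was 0.38 without FAP-no cilia replicate 3 (adjusted p = 0.0218), -0.60 without FAP-no cilia replicate 1 (adjusted p = 0.000573) and -0.42 without FAP-ctrl replicate 5 (adjusted p = 0.0118). With an estimated correlation none of these 3 calls held (adjusted p = 0.832, 0.625 and 0.766). Replication-dependent histones had 3 tested members and a median of -0.074 (adjusted p = 0.791). In all, camera called 10 lists as higher and 2 as lower; 0 lists were called with an estimated correlation or by fry, whose smallest adjusted p was 0.0721.

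The groups differed in the sex of the mice. Xist, the RNA that silences an X chromosome in females, stood between 16.6 and 118 in FAP-ctrl 1, FAP-ctrl 2 and all 3 FAP-no cilia libraries and between 19158 and 27801 in FAP-ctrl 3, 4 and 5, and the Y-linked gene Ddx3y between 3939 and 5235 in the former and between 0.868 and 32.6 in the latter. FAP-ctrl thus held 2 male and 3 female libraries and FAP-no cilia 3 male ones. In the 5 male libraries alone Ift88 had a log2 difference of -0.98, Ptch1 of 0.52, Gli1 of 0.75 and Timp3 of 0.54, and 10 of the 12 called lists were called again; macrophage and monocyte markers (median 0.30, adjusted p = 0.153) and immediate early genes (median 0.038, adjusted p = 0.922) were not. Among the lists called again, the median in the male libraries was 0.13 for Hedgehog target genes and 0.19 for hypoxia and glycolysis. It was 0.33 for cholesterol biosynthesis and -2.90 for erythroid markers. With an estimated correlation no list was called in the male libraries (lowest adjusted p = 0.522). The long noncoding RNA Malat1 and Rps24-ps3 passed the adjusted threshold there, both lower in FAP-no cilia, with log2 differences of -1.249 and -6.84.

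**Figure D3:**
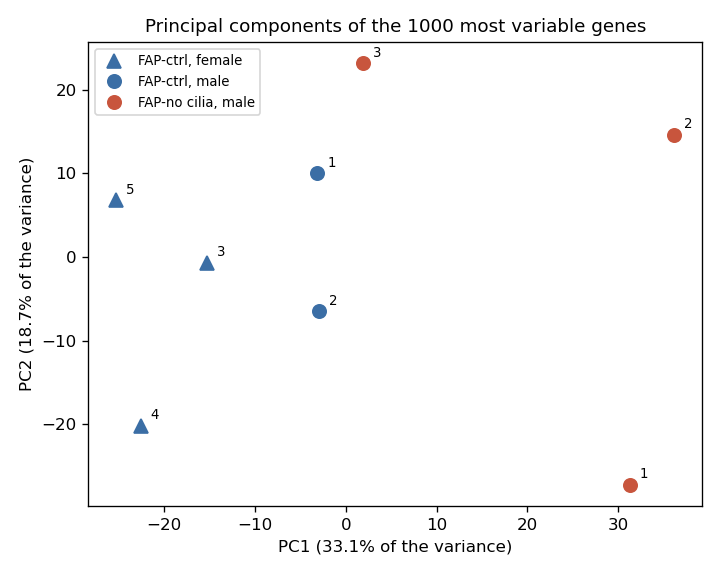
First and second principal components of log2(value + 1) of the 1000 most variable tested genes, with 33.1% and 18.7% of the variance; each point is a library with its replicate number, circles are male and triangles female. FAP-no cilia 1 (31.3) and 2 (36.2) lie apart on the first component, and FAP-no cilia 3 (1.86) lies near the male FAP-ctrl libraries (-3.13 and -2.99).

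Libraries correlated closely within and between the groups. Spearman's correlation of log2 values across the tested genes, which are not independent replicates, ranged from 0.983 to 0.992 within FAP-ctrl, from 0.986 to 0.989 within FAP-no cilia and from 0.979 to 0.989 between the groups. On the first principal component FAP-no cilia 3 lay near the male FAP-ctrl libraries, but on the second it had the highest value of all libraries (23.1). Its Ift88 value of 322 was the highest of its group.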

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

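The test for a library far from the others of its group applied to FAP-ctrl alone, as the other group has 3 libraries. It was fixed before the data were examined and marked 8 of 96 measures, where chance marks about 1 in 20, or 4.8 of 96. FAP-ctrl 5 stood apart in 4 of them. The median of the mitochondrially encoded genes in FAP-ctrl 5 was -0.83 (log2 deviation from the mean of each gene), against 0.20 to 0.40 in the other FAP-ctrl libraries, that of the erythroid markers -2.08 against 1.06 to 1.84, that of the cytokines and inflammatory genes -0.59 against -0.13 to -0.0054, and that of the TGF-beta and BMP signalling genes -0.18 against -0.020 to 0.044. FAP-ctrl 3 had the lowest median of the FAP identity markers, -0.33 against -0.027 to 0.097. FAP-ctrl 2 had the highest median of the hypoxia and glycolysis genes, 0.16 against -0.22 to -0.15. The heat shock chaperone gene Hspa8 had its lowest FAP-ctrl value in FAP-ctrl 4, 24200 against 26860 to 27800 normalized reads. FAP-ctrl 1 was the deepest library, with 43.9 M reads against 25.2 to 30.1 M.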

How the results depend on the processing

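The alternatives with edgeR and TMM factors, with sex as a covariate, with the male libraries and with DESeq2 and sex together were chosen after the data were seen. The count of 1 gene (0 higher, 1 lower) became 0 with robust edgeR (RLE, upper-quartile or TMM factors, or a mean CPM of at least 1), stayed 1 with TMM factors without robust dispersions, and became 0 with limma-voom, 16 with edgeR without a filter (9 higher, 7 lower), 177 with DESeq2 (74 higher, 103 lower) and 27 with DESeq2 and sex (10 higher, 17 lower). It was 2 in the male libraries (0 higher, 2 lower), 1 with limma-voom and quality weights (Angpt4; 1 higher, 0 lower), and 1 to 3 with a library left out (0 to 1 higher, 1 to 3 lower): 2 without FAP-ctrl 3 or FAP-no cilia 2 and 3 without FAP-no cilia 3. The cause of these differences was not tested. DESeq2 with sex compared males alone and kept 17 of 177 calls. Rps24-ps3 lost its call in 7 settings, with log2 differences from -7.16 to -6.62: the 4 edgeR fits with robust dispersions and a filter (RLE, upper-quartile and TMM factors, mean CPM), edgeR without a filter, and limma-voom without and with quality weights. Ift88 kept its direction in all 26 alternatives, with log2 differences from -1.37 to -0.93. It passed with edgeR without a filter (-1.11), DESeq2 (-1.10), DESeq2 and sex (-0.93) and without FAP-no cilia 3, and with a library left out it ranged from -1.37 to -1.01. Of the other named genes, 31 values newly passed. Of the 30 lists, 12 were called, and other settings gave 9 to 15, except camera with an estimated correlation and fry, which called 0. Over single lists, 64 values lost and 20 gained a call in the same direction. In the 11 limma-trend fits with a block, with sex as a covariate, of the male libraries or with a library left out, lists were called 119 times at the preset correlation and 0 times with an estimated one (lowest adjusted p = 0.272), a check added after the data were seen. Immediate early genes lost the call with a mean of at least 50 (adjusted p = 0.112), limma-voom with quality weights (0.10, adjusted p = 0.251) and both fits with sex as a covariate (0.038 and 0.050).

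Mmp14 was negative with sex as a covariate (-0.014), in the male libraries (-0.014) and with DESeq2 and sex (-0.014), and ranged from -0.012 to 0.14 with a library left out. Pparg was positive with the block (0.099), with sex as a covariate (0.21), in the male libraries (0.21) and with DESeq2 and sex (0.23), and ranged from -0.22 to 0.054. Cebpa ranged from -0.036 to 0.24 and Pdgfra from -0.12 to 0.029, and Pdgfra was positive with sex as a covariate (0.0024) and in the male libraries (0.0024). None of these 4 genes passed in any setting. Extracellular matrix and fibrosis genes were lower and called with sex as a covariate (-0.14), in the male libraries (-0.14) and with DESeq2 and sex (-0.14), at the preset correlation. With sex in the model the difference comes from the male libraries alone. The fits with sex and the male-only fit are thus not separate evidence, here or for Mmp14, Pparg and Pdgfra. Mitochondrially encoded genes ranged from -0.60 to 0.38 with a library left out, and were called as higher without FAP-no cilia 3 and as lower without FAP-no cilia 1, without FAP-ctrl 5 (-0.42) and with the replicate block (-0.40), each at the preset correlation only. Over all lists not called, 15 had a median that changed sign in a setting where they were not called either, 116 values from -0.28 to 0.73. Such changes were first counted with the reversals and were set apart after their number was seen.

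The replicate numbers did not in general pair the libraries: deviations of libraries with the same number correlated at -0.07, 0.135 and 0.036, and FAP-no cilia 1 and 3 correlated best with FAP-ctrl 4 (0.21) and FAP-ctrl 5 (0.35). FAP-no cilia 2 did correlate best with FAP-ctrl 2 (0.135), closely followed by FAP-ctrl 1 (0.129). FAP-ctrl 4 and 5 have no partner by number, so with the block they do not enter the difference. With the number as a block, 1 gene (0 higher, 1 lower) and 11 lists were called: interferon-stimulated genes (0.083, adjusted p = 0.226) and macrophage markers (0.33, adjusted p = 0.113) lost the call, mitochondrially encoded genes gained it (adjusted p = 0.0142; adjusted p = 0.945 with an estimated correlation), and Ift88 differed by -1.05. The planned sex covariate was not run as planned, as FAP-no cilia held male libraries only. Depth limits low genes most, as 1 read in FAP-no cilia 2 was worth 1.79 normalized reads.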

Other observations

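The tests of a fixed share of Rps24 reads and of sex for Rps24-ps3 were chosen after the result was seen, and so were the classes of noncoding RNA and the axonemal list as patterns to test. With sex as a covariate DESeq2 called 27 genes, a set also chosen after the data were seen, and 17 of them were among its 177 calls without sex. Among those lower in FAP-no cilia were Col6a6 (log2 difference -1.34) and Col20a1 (-1.31), which encode collagen chains, Hmcn1 (-0.94), the vitronectin gene Vtn (-1.04) and the tenascin gene Tnxb (-0.61). Myoc (1.34), the ferritin heavy chain gene Fth1 (0.52) and the retinoic acid hydroxylase gene Cyp26b1 (0.57) were higher. Of these genes, DESeq2 without sex also called Col20a1, Fth1 and Cyp26b1. It did not call Col6a6, Hmcn1, Vtn, Tnxb or Myoc. The share of false calls of DESeq2 with sex as a covariate was not simulated. Without sex it was 18.6%. With sex in the model the difference comes from 2 FAP-ctrl libraries in place of 5. A call lost there thus does not by itself show an effect of sex. Males against females within FAP-ctrl (2 and 3 libraries) gave 3 genes past the threshold, Eif2s3y, Uty and Xist, and 634 at an unadjusted p under 0.05. With so few libraries this does not exclude an effect of sex on other genes.

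Of the noncoding classes, 3 chosen after their values were seen were lower in FAP-no cilia, and processed pseudogenes were not (median 0.064 over 285, 134 of them lower). Only 4 miRNAs were tested, all of them lower (median -1.10), and they are not part of the chosen classes. The median log2 difference was -0.34 over 135 lincRNAs, -0.45 over 219 antisense transcripts and -0.64 over 53 snoRNAs, 50 of which were lower, against 0.017 over 13257 protein-coding genes. In the male libraries the medians were -0.19, -0.32 and -0.41. The deviation of the lincRNAs, antisense transcripts and snoRNAs together was -0.31 and -0.34 in FAP-no cilia 1 and 2 and 0.014 in FAP-no cilia 3, against -0.032 to 0.33 in FAP-ctrl. Within FAP-ctrl it was 0.123 and -0.032 in the male libraries and 0.237 to 0.332 in the female ones. FAP-no cilia 3 thus lay within the male FAP-ctrl values. Sex as a source of part of this pattern was not tested and stays open. The difference of the noncoding and protein-coding medians, -0.44, had an exact permutation p of 0.0357 (two-sided, 56 splits, not adjusted for the choice of the pattern or for sex), and ranged from -0.58 to -0.37 with a library left out.

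Read depth alone was argued against: with each library thinned to 15.3 M reads the difference kept 0.897 of its size (-0.40). Thinning cannot undo other properties of a library with a low yield, so these were not tested and stay open. The shallowest libraries, FAP-no cilia 2 (15.3 M reads), FAP-no cilia 1 (23.4 M) and FAP-ctrl 2 (25.2 M), had the lowest deviations (-0.341, -0.313 and -0.032). Deeper libraries did not keep this order: FAP-ctrl 5 (27.1 M) stood at 0.237, FAP-no cilia 3 (29.5 M) at 0.014 and FAP-ctrl 1 (43.9 M) at 0.123. Less genomic background stays open: reads of 1388 olfactory, vomeronasal and taste receptor genes were 39.1 ± 10.8 per M reads in FAP-ctrl and 33.1 ± 7.37 in FAP-no cilia, an exact one-sided permutation p of 0.214, which neither shows nor excludes it. These genes were chosen as silent in such cells and so can have little unspliced RNA of their own. Less unspliced RNA was therefore not tested by them and stays open. An effect of the genotype stays open as well. FAP-no cilia 3 did not share the lower value of the classes together, but its snoRNA median (-0.06) lay below every FAP-ctrl library (0.032 to 0.622). FAP-no cilia 3 also had the most reads of these receptor genes in its group, 41.4 per M reads against 27.2 and 30.6. The library without the lower pooled value is thus also the one with the most background reads of its group.

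Rps24-ps3 was the 1 gene past the threshold. Sex was argued against, as the lowest male FAP-ctrl value was 45.2 times the highest FAP-no cilia value. Reads shared with Rps24 stay a candidate source: all 353 windows of 50 bases in the pseudogene (a share of 1) lay within 2 mismatches of an Rps24 transcript, and 210 were identical to one. A fixed share of Rps24 reads was argued against, as the pseudogene stood at 2.86% to 13.0% of Rps24 in FAP-ctrl and at most 0.0528% in FAP-no cilia, a gap of 54.1 times, while Rps24 itself was at 7579 to 10698 and 10370 to 14348. A sequence variant of either copy between mice of the mixed background was not tested, as the reads were not used here, and a genotype effect stays open.

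The list called axonemal here held the 36 tested genes with the symbol stems Cfap, Dnah, Dnai, Dnaic, Dnaaf, Rsph, Drc, Tekt and Saxo. The genes were taken by name alone, and not every member need be a part of the motile axoneme. Their median log2 difference was -0.19, with 24 lower. Cfap74 (-1.91 ± 0.31), Saxo2 (-1.05 ± 0.22) and Dnah7b (-0.61 ± 0.14, SE) had the smallest p in limma-trend, where none of the 36 passed over all genes, while DESeq2 called these 3 (adjusted p = 6.23e-05, 0.0199 and 0.0201) and with sex as a covariate only Cfap74 of them (adjusted p = 0.0421, 0.563 and 0.610). Sex as the whole source was argued against, as the median in the male libraries was 1.117 times that in all 8, and these 3 genes differed there by -1.78, -0.93 and -0.54. The low level of these genes may account for the size of the median, which lay at the 11.2 percentile of 10000 random lists matched on mean level. The random lists drew on all tested genes, the lower noncoding classes among them, while the axonemal genes were protein-coding. The percentile thus does not separate a low level from the class of the genes. A genotype effect stays open: the medians per library were 0.033 to 0.188 in FAP-ctrl and -0.201 to -0.028 in FAP-no cilia, the median log2 difference had an exact two-sided permutation p of 0.0714, 8 members were lower and 0 higher at an unadjusted limma-trend p under 0.05, and camera with an estimated correlation gave a p of 0.0176, none of them adjusted for the choice of this list after its values were seen.

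Chance was not excluded for any of the counts in the comparison. Of the 56 splits of the 8 libraries into 3 and 5, the real one included, 6 gave at least 1 gene past the limma threshold (highest other split 10), 6 gave at least 1591 genes at an unadjusted p under 0.05 (highest other 1972), 4 gave at least 177 DESeq2 calls (highest other 208) and 8 gave at least 12 camera lists (highest other 15, median of the other splits 8). The split with 10 genes set the 3 female FAP-ctrl libraries against the 5 male ones and so follows sex. The splits with 1972 and 208 set FAP-ctrl 2 with FAP-no cilia 1 and 2 against the others, FAP-no cilia 3 among them.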
